A study of Mus musculus with 2 samples.

How the data were processed

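Total RNA of mouse mammary glands was labelled with Cy3 after linear amplification, per the labels' protocols, and hybridised to 1 Agilent array per genotype, with 180880 spots each. The intensity values deposited for each array are scanner output of Agilent Feature Extraction, whose version is 10.7 in the submitters' processing notes and 11.5.1.1 per the file headers. The processed signal in these files is background-subtracted intensity, per the file headers, and is not scaled between arrays. The authors' deposited table holds log2 values, whose scale was worked out from the files: each column equals log2 of the processed signal minus a constant, 8.40 for the control and 7.95 for the knockout, for 100% of probes to within 0.0001. Its columns have medians of -1.94 and -1.95 and 75th percentiles of 0, so scale and centring are known. The direction of every difference here is knockout minus control.

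Groups were taken from the genotype in the sample labels. Control spots and spots with an outlier mark (0.893% of the control array and 0.430% of the knockout array) were left out. The log2 processed signals of a probe's spots were averaged, and the 75th percentile of each array over 97373 probes with a usable spot on both arrays was subtracted, 8.36 for the control and 7.92 for the knockout. A probe was measured on an array when all its usable spots were well above background. A probe seen on 1 array only was given a bound, the bright level minus the higher of the lowest level among probes well above background on the other array and the dim level itself. Probes whose spots disagreed in this call (5981 over both arrays) had no value. A difference of at least 2-fold was called by size. The planned design rested on 1 array per genotype and held no test.

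Probes were classed by the database prefix of their names, and all classes other than the Agilent catalogue were counted as lncRNA probes, although some RIKEN clones belong to protein-coding genes. Names came from a RefSeq gene table of assembly GRCm38.p6, used for names and for which genes neighbour each other. Through accessions 4658 probes were named, through RIKEN clone names 1209 and through names written on the array 5, while 5 probes that matched several genes were left unnamed. Of 13017 RefSeq probes 4656 matched, and of 15675 RIKEN probes 1209. None of the Agilent catalogue probes carried a name. They were taken as mRNA probes by their prefix, which was not checked. A gene's value was the mean of its measured probes, and 55 of 155 genes with several probes had probes of opposite sign. Such genes were not named individually unless a fixed list held them. The planned comparison of genes with miR-34a seed sites needed transcript sequences and was not analysed here.

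Before the data were examined, the named genes were fixed as the title's transcripts, the 12 largest increases and 12 largest decreases of genes at least 2-fold apart whose probes had 1 sign and whose brighter level was above the array's median of measured genes, the 4 largest members of each list, the 3 largest bounds each way, and the 4 largest lncRNA transcripts each way. After the data were opened, the rule for the 12 was applied to protein-coding genes named through clones or accessions. The 8 largest lncRNA genes with a symbol each way, the genes beside list members and the windows of NONCODE numbers were then added. Of the 4 lncRNA transcripts each way, at most 2 identifiers were printed. A few genes that these rules picked are not reported here. Of the 33 fixed lists, those with at least 3 measured genes were set against 10000 random lists of the same size in 20 bins of mean signal, and called extreme at or beyond the 1st or 99th percentile. For the NONCODE probes, the median of 15 consecutive usable probes was compared with 1000 shuffles of their order.

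Alternatives were scaling to the median of detected probes, quantile and loess scaling, the authors' table, no filter on dim probes, a stricter filter, outlier spots kept, other ways to combine probes, and limits of 1.5-fold and 4-fold. The planned background alternatives on mean spot signals were not run, because that column was not in the files used here. Normexp with an offset of 50 (limma 3.58.1 in R 4.3.3) and no correction, both on median spot signals, and scaling to 9 E1A spike-in probes were added after the data were seen. Calculations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. In simulated arrays of 69405 probes, every probe was given the same noise, the median spot SD as for a mean of 2 spots. There the calls found 100% of probes changed 3-fold, 4-fold or 8-fold, 0 of 50 changed 1.5-fold, and 0 of 69205 unchanged. These figures follow from that small and equal noise. They do not cover noisier probes, probes with 1 spot or variation between animals. Apart from this, of 200 unchanged lists of 10 drawn from 1500 simulated normal differences, 6 were called extreme.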

Results

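RNA from the mammary gland of female mice was measured on 2 one-colour Agilent arrays that carried probes for mRNAs and for long non-coding RNAs (lncRNAs). One array held a control gland with floxed miR-34a alleles (miR-34a fl/fl), and the other a gland in which a mammary-specific Cre recombinase had deleted miR-34a (knockout). With 1 array per genotype there was no replicate, so no test was made, no p-value is given, and every difference describes these 2 glands. The number of arrays limits the precision of all values. On the control array 77.3% of the 175906 non-control spots were well above background, and on the knockout array 75.4%. The median spread between the 2 spots of a probe was 0.09 log2 units (SD) on each array, and no spot was saturated. This spot spread covers printing and scanning only, not animals, dissection, labelling or hybridisation.

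The first question was whether miR-34a itself marked the knockout. No probe on the array could be matched to Mir34a through the gene table, so the labels could not be checked on the deleted gene. Adam12, a membrane metalloprotease named in the series title, was in the same position: mRNA probes carried Agilent catalogue identifiers that the sources used here do not pair with genes. A single named lncRNA gene, 5830403F22Rik, overlaps Adam12. Its probe was higher in the knockout, at 0.23 against -1.11 in the control (log2 signal relative to the 75th percentile of the array), a 2.54-fold difference. With the added spike-in transcripts set equal on both arrays the log2 difference was 0.99. The probe was picked through the gene table after the data were opened, it belongs to another transcript, and it gives no value for Adam12.

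The lncRNA named in the title, lnc015192, was found by its number as a NONCODE transcript with 2 spots per array. That title belongs to the series of these 2 arrays, so lnc015192 may have been chosen from these same values. It was well above background in both spots of the knockout array and in neither spot of the control array. The processed signals were 58.5 and 53.8 in the knockout gland, against 3.18 and 2.93 in the control gland. The control level only sets a bound, by which lnc015192 was at least 5.33-fold higher in the knockout (log2 2.42). The log2 bound was 1.31 with normexp background correction and 1.89 with no background correction. In the knockout its signal stood at percentile 54.2 of the NONCODE probes, a rank of probe signals and not a measure of transcript amount. Transcripts with neighbouring NONCODE numbers were also higher: of the 15 usable probes centred on lnc015192, 13 lay above 0 and 10 were at least 2-fold higher, 6 of the 15 being well above background on the knockout array only. Their median log2 difference, with probes seen on 1 array only set at their bound, was 1.29. All NONCODE probes measured on both arrays had a median of 0.11. With the spike-ins set equal 6 of the 15 were at least 2-fold higher and their median was 0.94, and with normexp these were 4 and 0.82. The numbers are identifiers, and the genomic positions of these transcripts were not used here. Whether these probes read separate RNAs is therefore unknown.

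**Figure D1:**
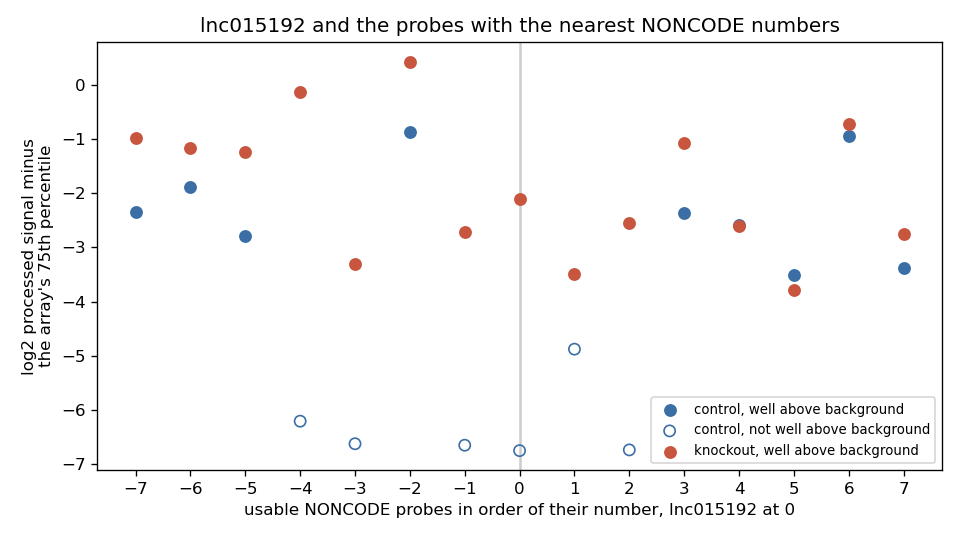
Level of lnc015192 (position 0) and of the 14 usable probes with the nearest NONCODE numbers, as log2 processed signal minus the 75th percentile of the array, 1 point per array. Filled points were well above background and open points were not; 6 probes, lnc015192 among them, were measured on the knockout array only.

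The next comparison asked which mRNAs differed between the glands. Among probes of the Agilent catalogue, taken as mRNA probes by the prefix of their names, 30608 of 38719 were well above background on both arrays. Of these 1477 were at least 2-fold higher and 1797 at least 2-fold lower in the knockout. The sizes were lopsided: 80 of these probes were at least 16-fold lower and 4 at least 16-fold higher, and the extremes among probes measured on both arrays were 290-fold lower and 29.5-fold higher. A further 770 probes were well above background in the control only, with bounds up to at least 1036-fold lower, and 205 in the knockout only, with bounds up to at least 19.96-fold higher. Within an array, 2 spots of the same probe differed by at least 2-fold in 0.355% of pairs on the control array and 0.495% on the knockout array. Calls near the limit were less firm. Over all probe classes, 74.4% of 2318 probes with 2 spots called higher were past 2-fold in both spots. For those called lower it was 83.5% of 2496. The direction of the split between higher and lower depends on the setting. It was 935 higher and 722 lower among probes with both signals above the array's median of detected probes, and 4840 and 3694 at 1.5-fold. Setting the added spike-in transcripts equal on both arrays moved every difference by -0.36 and left 618 higher and 3312 lower.

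**Figure D2:**
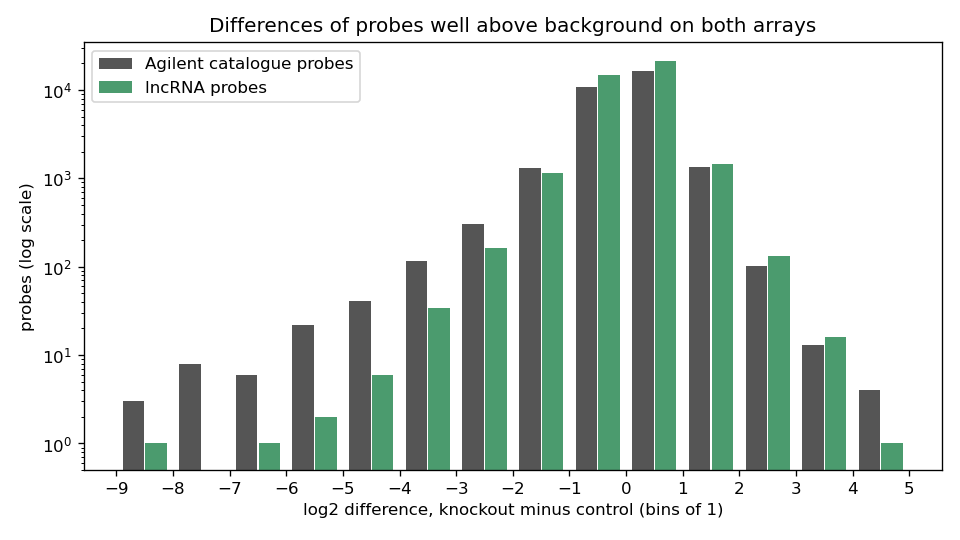
Number of probes (log scale) in each bin of log2 difference, knockout minus control, for probes well above background on both arrays. Both classes have their highest bins at 0 to 1, and the Agilent catalogue probes reach further down, to between -9 and -8, than up, to between 4 and 5.

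Protein-coding genes could be named only where a RIKEN clone name or an accession on the array matched the gene table, which gave 525 measured genes. Of these 18 were at least 2-fold higher and 27 at least 2-fold lower in the knockout. Such probes were made for cDNA clones and need not represent the main transcript of the gene. Exph5, a Rab27-binding protein of vesicle transport, was 15.4-fold lower, at -3.53 in the knockout against 0.42 in the control. Mpzl3, an immunoglobulin-like membrane protein whose loss affects skin and hair, was 7.88-fold lower. Scnn1b, a subunit of the epithelial sodium channel, was 2.86-fold lower. Dst, a cytoskeletal linker that includes the hemidesmosome form, was 2.54-fold lower, through a probe of a locus that overlaps Bend6. The membrane proteins Tmem132c and Lrrn1 were 8.84-fold and 6.76-fold lower. Acpp, an acid phosphatase, was 4.54-fold lower. The actin-binding Synpo2 was 2.56-fold lower as the mean of 2 probes. Ttc7 (3.55-fold), Yod1 (3.23-fold), Arhgef5 (3.04-fold) and Ndfip2 (2.48-fold) completed the 12 largest decreases. The locus of Yod1 overlaps Pfkfb2.

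The largest increase of a named protein-coding gene was that of Pde3b, the cyclic nucleotide phosphodiesterase through which insulin restrains fat breakdown in adipocytes. It was 6.03-fold higher, at 0.32 in the knockout against -2.27 in the control. Hhipl1 was 3.34-fold higher and the tetraspanin Tspan18 3.32-fold. Lamb1, a laminin chain of basement membranes, was 3.16-fold higher. The enzyme Dhdh, whose locus overlaps Tulp2, was 3.11-fold higher. The leucine-degrading Ivd was 2.81-fold higher, the glutathione transferase Mgst3 2.76-fold and the monooxygenase Fmo2 2.29-fold. Paqr9 (2.68-fold), the RNA-editing enzyme Adarb1 (2.59-fold), Mcf2l (2.26-fold) and Fbxw8 (2.14-fold) completed the 12. The largest spot SD among all named genes with 2 spots was 0.57 log2 units, and the median was 0.17. Exph5, Mpzl3, Yod1, Scnn1b, Dst, Lamb1, Dhdh, Ivd, Paqr9, Mcf2l and Fbxw8 had 1 spot per array, so their spot spread is unknown. With normexp background correction Exph5 was at -2.28, Tmem132c at -2.41, Mpzl3 at -1.86, Acpp at -1.38, Yod1 at -1.06 and Pde3b at 1.76 on the log2 scale, each a fold over 1.5 times smaller. With it Ttc7, Dst, Ndfip2, Hhipl1, Ivd, Mgst3, Paqr9, Adarb1, Fmo2 and Fbxw8 kept their direction at less than 2-fold. With the spike-ins set equal, Fmo2, Mcf2l and Fbxw8 were also under 2-fold.

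**Figure D3:**
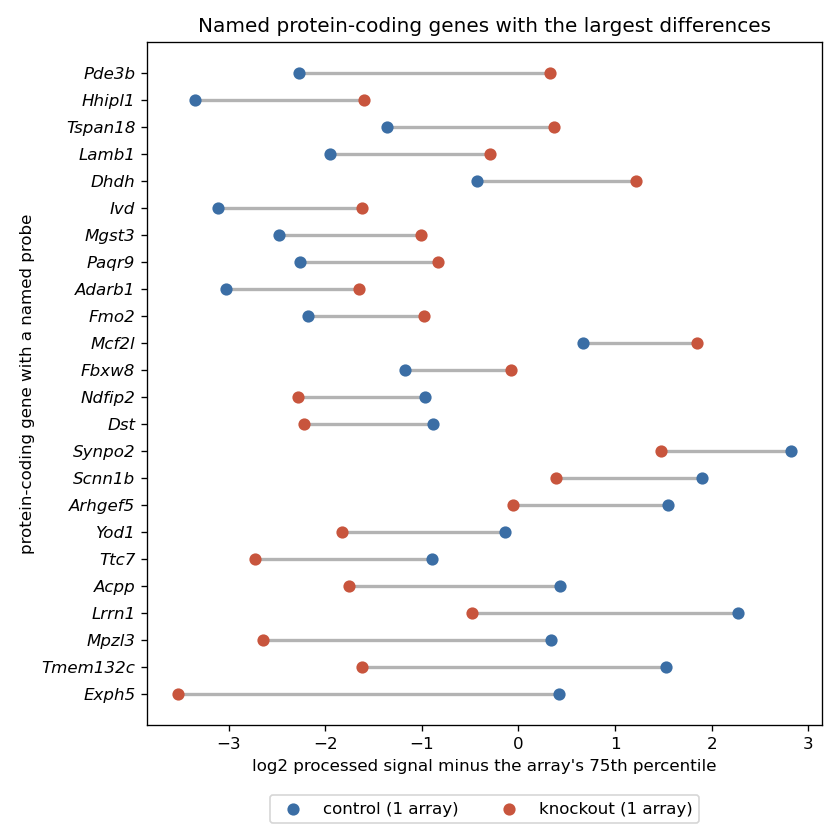
Levels of the 12 named protein-coding genes with the largest decrease and the 12 with the largest increase, as log2 processed signal minus the 75th percentile of the array. Each point is 1 array and the grey line is the difference, from -3.94 for Exph5 to 2.59 for Pde3b.

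Among genes with a symbol that were above background in 1 gland only, the largest bounds were on the control side. Serpina3h, a transcribed pseudogene of the antichymotrypsin family, was at least 72.2-fold lower in the knockout. Gm35639, a lncRNA gene overlapping Smcp and, with it, Lce6a and Lce1a1 of the cornified envelope cluster of the epidermis, was at least 28.0-fold lower. Tprg, which lies beside Trp63, was at least 16.7-fold lower. On the knockout side 4931422A03Rik, at least 4.67-fold higher, and A930027H12Rik, at least 3.60-fold, had the second and the third largest bounds. In all, 116 named genes were seen in the control only and 67 in the knockout only.

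For the lncRNA comparison, 38797 of 58654 probes were well above background on both arrays. Of these 1609 were at least 2-fold higher and 1355 at least 2-fold lower in the knockout, and 846 further probes were seen in the knockout only and 1680 in the control only. NONCODE probes were higher more often than lower (799 against 593), as were RefSeq probes (303 against 213), while RIKEN clone probes were not (479 against 528). The split over all lncRNA probes follows the scaling. With the spike-ins set equal the lncRNA counts were 646 higher and 3355 lower, and with a loess curve 1268 and 1653. Among lncRNA transcripts measured on both arrays, the largest decreases were those of NONMMUT044076, 309-fold lower, and NONMMUT023938, 71.6-fold lower. The largest increases on that basis were those of NONMMUT073821, 23.8-fold higher, and the RIKEN clone C130075O13, 13.0-fold higher. NONMMUT044076, NONMMUT073821 and C130075O13 each had 1 spot per array, so their spot spread is unknown. Probes seen on 1 array only were not ranked with these, and their bounds reached 369-fold lower and 35.1-fold higher.

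Among genes with a symbol, 2643 of a biotype other than protein-coding were measured, most of them lncRNA genes and others mainly transcribed pseudogenes, of which 114 were at least 2-fold higher and 75 at least 2-fold lower. Rnf227, listed as a lncRNA gene between Kcnab3 and Chd3, was 22.8-fold lower, at -1.79 against 2.73 in the control. Gm32255, which overlaps the immediate early gene Egr2, was 20.6-fold lower. C530043A13Rik, between Tnp1 and Tns1, was 9.82-fold lower. Gm39718 (7.59-fold), Gm39323 beside Thy1 (7.05-fold), Gm31657 (5.20-fold) and Gm45918 (4.97-fold) were also among the 8 largest decreases. In the other direction Gm39540, overlapping Ribc1, was 12.4-fold higher and 8430415O14Rik, overlapping Fam13a, 10.3-fold higher. The lncRNA gene 0610005C13Rik, which overlaps Bcat2, was 7.83-fold higher. A730049H05Rik, overlapping Adamts9, was 4.82-fold higher. 8430415O14Rik and A730049H05Rik had 1 spot per array. Gm40921 (4.94-fold), Gm40325 beside Aacs (4.69-fold) and 4930588K23Rik beside Tbx1 (4.38-fold) were also among the 8 largest increases. With normexp the log2 differences of several were smaller by over 1.5 times in fold: Rnf227 was at -3.76, Gm32255 at -3.13, Gm39718 at -1.35, Gm39323 at -1.53 and Gm31657 at -1.73. Likewise Gm39540 was at 2.54, 0610005C13Rik at 1.74 and 4930588K23Rik at 1.48.

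Of the gene lists fixed before the data were examined, the one for imprinted and nuclear lncRNAs had enough named probes for a median. Of its 11 measured members 8 were above 0 and 1 was at least 2-fold higher. The median log2 difference of the list was 0.16, at percentile 58.1 of 10000 random lists matched on signal, so the list as a whole did not stand apart. All measured genes with a symbol had a median of 0.11, so most genes lay above 0. Rian, a maternally expressed lncRNA of the Dlk1-Dio3 region, was higher by 2.22 at a RefSeq probe and by 0.39 at a RIKEN probe. Its neighbours in that region, Meg3 and Mirg, were higher by 0.56 and 0.47, and the snoRNA host Snhg5 by 0.68. Hotair and Rmst were at -0.24 and -0.25. With the spike-ins set equal the list median was -0.20, while Rian, Snhg5, Meg3 and Mirg stayed above 0. Rian, the single member at least 2-fold higher, was then at 0.95 and no longer called. In other lists Zeb2 (-0.08), Kif2c (-0.07), Mx2 (0.38) and Cry2 (0.25) were the measured members. The lists of miR-34a targets and of mammary cell types had no measured member with a name.

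Because the list members lacked named probes, lncRNA genes and the few pseudogenes or other non-coding genes that overlap or flank a member were described in their place, a choice made after the data were opened. Of the 29 lists with at least 3 such genes, 2 reached the 99th percentile of random lists and none the 1st. Among simulated unchanged lists 6 of 200 were called extreme, so a list among 29 can pass with no shared change. The median over all measured non-coding genes with a symbol was 0.13. Most such genes thus lay above 0, and counts above 0 lean that way in any list. Neighbours of white adipocyte genes had a median of 0.99 at percentile 99.9, with 4 of 5 above 0. C730014E05Rik, beside the adipokine gene Adipoq, was 1.99-fold higher, Gm36301, beside Pparg, 1.94-fold, Gm33103, beside the lipase gene Lpl, 2.24-fold, and 4732471J01Rik 2.09-fold. The last overlaps the lipase gene Lipe but also Cxcl17, Ceacam1 and Ceacam2, and its 2 probes differed, at 0.58 and 1.55. Gm38779, beside Lep, was at -0.08. The other fat-related lists did not stand apart: neighbours of brown and beige adipocyte genes had a median of 0.12 at percentile 39.1, with 4 of 6 above 0, and those of lipogenesis genes -0.07 at percentile 12.6, with 3 of 7. Neighbours of ADAM family genes had a median of 0.58 at percentile 99.02, with 5 of 7 above 0, among them 5830403F22Rik and A730049H05Rik. The gene at that median, 9530026P05Rik, overlaps Adamts9 as A730049H05Rik does, so the 7 are not all separate loci. The ADAM median was 0.23 without the filter on dim probes and 0.22 with the spike-ins set equal. The lists next to these were those of cholesterol synthesis, at percentile 98.0, and common reference genes, at percentile 97.3 with a median of 0.47. Neighbours of miR-34a targets had a median of 0.22 at percentile 87.5, with 29 of 45 above 0. Neighbours of luminal epithelial genes were at percentile 93.2 with a median of 0.36, and those of hormone-responsive genes at percentile 2.77 with a median of -0.25. The lowest percentile was that of skeletal muscle, 2.39, with a median of -0.33. Neighbours of keratinocyte and hair genes had a median of -0.13, at percentile 11.2. In the main setting, genes seen on 1 array only had no part in these medians. The keratinocyte set thus left out Gm35639, which flanks Ivl and was seen in the control only. A non-coding gene can change apart from the gene beside it, so these values describe the non-coding genes only.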

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

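The tests in this part were chosen after the result was seen. Control spots for Gapdh and Pgk1, which no comparison used, were higher on the knockout array than on the control array after scaling. The log2 difference was 1.53 at the 5' Gapdh spots, 1.19 at the 3' Gapdh spots, 0.89 at the 5' Pgk1 spots and 0.57 at the 3' Pgk1 spots. The 3' minus 5' level moved by -0.33 for Gapdh and by -0.32 for Pgk1 from control to knockout. Scaling does not account for the Gapdh difference, since the smaller one was still 0.84 with the spike-ins set equal, against an SD of 0.18 between spike-in probes. The Pgk1 differences were then 0.53 at the 5' spots and 0.21 at the 3' spots, the latter close to that SD, so scaling is not excluded for 3' Pgk1. Loss of 5' ends in the control RNA alone would leave the 3' Gapdh spots level, and these differed by 1.19. Genotype, the makeup of each tissue piece and the condition of each RNA remain open and untested, because each genotype is 1 gland.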

How the results depend on the processing

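The settings on median spot signals and on spike-ins were chosen after the data were seen. Counts are given as Agilent catalogue probes, lncRNA probes and genes with a symbol, each higher then lower. The main counts were 1477 and 1797, 1609 and 1355, and 132 and 102. With normexp they were 790 and 1095, 521 and 451, and 40 and 34. With no background correction the lncRNA probes were 792 and 571 and the genes 64 and 46. Without the filter on dim probes they were 2491 and 2834, 4271 and 3244, and 400 and 257. With both signals above the median of detected probes they were 935 and 722, 443 and 277, and 34 and 22. With the spike-ins equal they were 618 and 3312, 646 and 3355, and 54 and 239. At 1.5-fold they were 4840 and 3694, 5531 and 3869, and 455 and 271, and at 4-fold 120 and 502, 148 and 205, and 10 and 16. The share of higher among called probes was 49.5% in the main setting, 38.5% with loess, which moved the median difference by -0.11, and 15.9% with the spike-ins, which moved it by -0.36. The other scalings, the authors' table and the kept outlier spots left every count within 1.5 times. The authors' table holds the same signals less a constant per array, so its match was set in advance.

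The log2 bound of lnc015192, 2.42, was 2.16 with loess, 1.31 with normexp, 1.89 with no background correction, 2.06 with the spike-ins equal, and 4.65 as a plain difference without the filter. It stayed above 1 in each. The median of the imprinted and nuclear lncRNA list, 0.16, was 0.32 with the stricter filter and -0.20 with the spike-ins equal, which lowers every difference alike. Of the 15 probes around lnc015192, 10 were at least 2-fold higher, against 4 with normexp and 6 with the spike-ins equal, a count added after the data were seen. Medians of the non-coding genes beside white adipocyte genes ranged from 0.63 to 0.99, and beside ADAM genes from 0.22 to 0.74. Apart from shifts that follow from a setting's construction, the cause was not tested. Of 450 values of the 40 protein-coding and lncRNA genes that the rules picked under the alternatives, none changed sign and 432 stayed at least 2-fold. These genes were picked for differences of at least 2-fold, and some settings leave the value of a gene with 1 probe as it was. The count was thus largely set in advance and says little about stability. The normexp offset of 50 is added to every spot, so by construction it shrinks the log2 differences of dim probes most. How much of the shifts with normexp this accounts for was not tested. Alternatives for Adam12 and for seed sites, and those on mean spot signals, were not run. No paired analysis was possible because each genotype has 1 array.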

Other observations

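The tests in this part were chosen after the result was seen. Runs of consecutive NONCODE numbers that differed together were looked for along all NONCODE probes. The order of the numbers carried information, since consecutive usable probes correlated at a Spearman rho of 0.14 across 20554 probes, which are not independent replicates, against at most 0.02 in 1000 shuffles. The highest window of 15 probes, which holds lnc015192, had a median of 1.55 with 12 probes at least 2-fold higher. The next separate window had a median of 1.01, below the highest of any shuffle (1.12). On the lower side 2 separate windows had medians of -1.33 and -1.18, each with 9 probes at least 2-fold lower, past the lowest of any shuffle (-1.05).

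The presence of lnc015192 on the knockout array only was weighed against technical causes. A spot or local background artefact would leave the raw spot medians level in at least 1 spot, and the smaller log2 ratio of the 2 spots was 1.45. A less sensitive control array would show more probes on the knockout array only, but probes seen on the control array only were 2.33 times as many. The 14 neighbouring probes without lnc015192 had a median of 1.26, above every shuffle. Under the alternatives this held except without the filter on dim probes, where 1 of 1000 shuffles reached it, and with the stricter filter, which left 8 of the 15 probes and where 2 shuffles did. A hypothesis is that lnc015192 may be part of a difference shared by probes of neighbouring numbers. The shuffles treat probes as separate. Whether these probes read the same RNA was not checked, so the comparison cannot show that separate transcripts differed. Genotype, other differences between the 2 mice, RNA condition and array handling cannot be separated with 1 gland each. None of these was tested.

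Decreases of at least 16-fold (90 probes) outnumbered increases of that size (5 probes). An intensity-dependent difference between the arrays is argued against by the loess curve, after which 95 decreases and 5 increases of that size were left. Single bad spots are argued against too, since 92.2% of the 77 such probes with 2 spots were past 16-fold in both. A different share of skin or hair in the pieces of gland could contribute, given the lower Gm35639 in the cornified envelope cluster. The non-coding genes beside keratinocyte and hair genes had a median of -0.13 over 4 genes measured on both arrays. That set left out Gm35639, which flanks the list gene Ivl and was seen in the control only, so the median decides nothing. A different share of skin or hair cannot be told apart from an effect of genotype, because neither genotype has a replicate gland. Most of the probes concerned also have no name here.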
